A study of Zea mays with 12 samples.

How the data were processed

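Maize seedlings of the lines Mo17 and Chang7-2 were inoculated 6 days after planting with 0.01 M phosphate buffer or SCMV, with at least 15 seedlings per treatment, and grown at 28 degrees C for 16 hours and 22 degrees C for 8 hours, per the labels. Leaves were taken 10 days after inoculation. Ribosomal RNA was depleted and libraries were strand-specific, per the labels. The 12 libraries formed 4 groups of 3. Small RNA and degradome libraries of the series were not analysed here.

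The table of genes held estimated counts, rounded up to whole numbers, and FPKM, both made by the authors from assembled transcripts and deposited as 1 value per locus and library. Across 1681 low values, 96.7% of the deposited counts lay between 0 and 1 above the value their FPKM implied. The table of circRNAs held back-splice counts and SRPBM (back-splice reads scaled by mapped reads), both made by the authors and used as deposited. The aligner, assembler and circRNA caller are not given in the sources used here for these tables. The submitters' processing notes name Bowtie 0.12.2 and the mouse build mm8, which cannot describe tables with maize coordinates. Identifiers of the form Zm00001d and the contig names of the tables belong to B73 RefGen_v4, and the symbols and descriptions were those of the authors' table.

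Total counts in replicates 1, 2 and 3 were 119.0, 117.7 and 126.0 M in Mo17 mock, 106.7, 103.8 and 108.7 M in infected Mo17, 126.5, 118.5 and 118.7 M in Chang7-2 mock and 116.7, 117.6 and 119.3 M in infected Chang7-2. Nuclear genes held 28.2 to 32.2 M counts per library. Of the 32795 loci tested, 23392 held a single nuclear gene, 717 held at least 2 annotated features, 8307 held none and 250 were encoded in organelles. Spearman correlations within groups were 0.947 to 0.982, and no pair of replicates was identical over all loci (7.00 to 8.83% of loci held the same value in a pair).

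Groups, comparisons, alternatives, gene lists and the rule for naming genes were set before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests on the estimated counts of all 12 libraries, with its count filter, TMM factors and 4 group means. The 5 comparisons were the response to SCMV in each line, the difference of these responses (Mo17 minus Chang7-2), and Chang7-2 against Mo17 without and with infection. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 counted as a call. CPM used TMM factors. For circRNAs, a fold against a group with 0 counts was given as at least the ratio to a floor of 3 counts over the group, and against 1 to 3 counts as a ratio with a 95% counting interval. The interval and the floor treat counts as independent reads. For genes the totals of estimated counts exceed the mapped reads that the SRPBM values imply (30.9 to 40.2 M per library), so they are not single reads. Several genes with few or no estimated counts in a group were given as estimated counts without a fold, floor or interval. Others near 0 CPM in a group were given as log2 differences, which rest on few estimated counts.

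Gene lists were matched on symbols and descriptions in the authors' table, and lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The 26 lists were photosystem and light-harvesting proteins, Calvin cycle and C4 cycle enzymes, chlorophyll biosynthesis, pathogenesis-related proteins, WRKY transcription factors, NLR-type receptors, RNA silencing, jasmonate biosynthesis and JAZ repressors, the phenylpropanoid, lignin and flavonoid pathway, the benzoxazinoid pathway, the terpenoid defence pathway, cytosolic and plastid ribosomal proteins, heat shock proteins and chaperones, glutathione S-transferases and antioxidant enzymes, autophagy, the 26S proteasome, the circadian clock, starch and sucrose metabolism, senescence-associated genes, cell cycle and replication-dependent histones, epidermal wax and cutin, vascular and phloem markers, auxin response, initiation factors 4E and 4G, and genes encoded in mitochondria and plastids. Members were also adjusted over their list alone.

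Genes were named by a fixed rule. Named were the 8 loci with the largest rise and the 8 with the largest fall among calls with a mean FPKM of at least 5, no overlap between the libraries of the groups, and a symbol or description (5 and 5 for the difference of responses and for infected lines). Overlap was not checked for the difference of responses. Up to 2 called members of each list in each direction, genes tied to SCMV in earlier work, and markers of mesophyll and bundle sheath were added. The choice of which list members the text shows was made after the data were seen.

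CircRNAs with counts above 0 in at least 3 libraries were tested with the same edgeR fit. Numbers and totals of circRNAs per library were compared by two-sided exact permutation tests. Symbols and descriptions given for the host conflicted for circRNA180, circRNA339, circRNA945 and circRNA483.

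Alternatives were DESeq2 1.42.0 with its size factors, limma on log2 FPKM with pseudocounts of 1, 0.5 and 0.1, TMM factors on FPKM, quantile normalization, other filters, a replicate block, fits on the libraries of 2 groups only, and each library left out in turn. Library totals as the only scaling, fits without the first mock library of each line, loci of 1 annotated nuclear gene, fits without circRNA483 and ciRNA365, and DESeq2 on circRNAs were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

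The fits were tested on simulated data. For the response in Mo17, among 31842 simulated loci with 50 changed at each size, 40% of the 2-fold and 82% of the 4-fold rises and 32% of the 2-fold and 58% of the 4-fold falls were recovered, with 3 false calls. A list shifted 2-fold was called and 0 other lists were, but loci were simulated independently of each other. Members of real lists can be correlated (0.349 for the photosystem list in Mo17). The simulation therefore does not show how often an unshifted list is called in real data. Of 20 circRNAs changed 8-fold in Mo17 among 360, 50% were recovered, with 0 false calls.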

Results

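Gene expression was compared in leaves of 2 maize inbred lines, Mo17, which is susceptible to sugarcane mosaic virus (SCMV, a potyvirus), and Chang7-2, which is resistant to it. Seedlings received buffer (mock) or SCMV, and leaves were taken 10 days later, with 3 libraries in each of the 4 groups. Infected is used here for leaves of seedlings that received SCMV. Virus RNA was not measured, so the amount of virus in the leaves of either line is not known. Total counts, in M (1e6 counts), ranged from 103.8 to 126.5 M per library. Mean totals (± SD, n = 3) were 121 ± 4.47 M in Mo17 mock, 106 ± 2.49 M in infected Mo17, 121 ± 4.57 M in Chang7-2 mock and 118 ± 1.31 M in infected Chang7-2. The 10 most abundant loci held 64.0 to 72.5% of the counts of a library, and genes encoded in plastids and mitochondria held 12.6 to 14.5%. Of 40394 loci, 32795 passed the count filter and were tested.

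The first principal component held 74.0% of the variance and separated the lines, with Mo17 libraries at 184 to 203 and Chang7-2 libraries at -199 to -196. The second held 6.75% and separated the treatments, with Mo17 mock at 64.1 to 101 and infected Mo17 at -91.7 to -73.3, and Chang7-2 mock at 15.6 to 29.5 and infected Chang7-2 at -23.7 to -20.2. The third spread libraries within 3 of the groups: replicates 1, 2 and 3 lay at -82.0, -9.19 and 64.9 in Mo17 mock, at 7.00, 72.2 and 70.3 in Chang7-2 mock and at -78.5, -58.8 and -13.4 in infected Chang7-2. Infected Mo17 lay at 6.37, 4.78 and 16.3. On this component all Chang7-2 mock libraries also lay above all infected Chang7-2 ones, while Mo17 mock libraries alone ranged from -82.0 to 64.9. Part of the difference between treatments in Chang7-2 thus lay along an axis that varied without infection as well. The TMM scaling factor averaged 0.843 ± 0.0626 (SD, n = 3) in Mo17 mock and 1.25 ± 0.0315 in infected Mo17, so the scaling weighed on every change in that line. Scaled by library totals alone, the median log2 change of all loci was 0.53 in place of 0.00 for infection in Mo17 and 0.17 in place of 0.00 in Chang7-2. It was 0.36 in place of -0.02 for the difference of the responses, 0.13 in place of 0.01 between lines without infection and -0.30 in place of -0.03 between infected lines. All changes are given relative to TMM scaling. The labels do not say whether the 3 replicates came from separate plants or pools, so p-values measure only the spread between these samples.

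In infected Mo17, transcripts of chlorophyllase2, an enzyme that cleaves chlorophyll, rose from 4.51 ± 1.32 to 51.8 ± 5.46 CPM (counts per M, TMM-scaled; mean ± SD, n = 3). The log2 change was 3.52 (SE 0.302; adjusted p = 8.69e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). A locus of phenylalanine ammonia lyase9 and 8, which open the phenylpropanoid pathway, rose from 11.7 ± 2.03 to 130.5 ± 18.9 CPM, and the neighbouring phenylalanine ammonia lyase homolog1 rose from 17.5 ± 4.56 to 130.9 ± 24.7 CPM. Pathogenesis related protein5, a defence marker, rose from 12.2 ± 2.19 to 66.8 ± 10.97 CPM. Chlorophyll a-b binding protein of LHCII type III, an antenna protein of photosystem II, fell from 676.6 ± 19.4 to 35.7 ± 4.17 CPM, a log2 change of -4.24 (SE 0.0888; edgeR adjusted p = 5.48e-11). Photosystem II light harvesting complex gene 2.1 fell from 346.1 ± 17.3 to 23.8 ± 1.79 CPM, and aluminum-induced protein homolog1 fell from 539.4 ± 144 to 33.8 ± 3.18 CPM.

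These loci were placed by the identifiers and contigs of B73 RefGen_v4. Chlorophyllase2 (Zm00001d032926) lies on chromosome 1 from 243418415 to 243419837, and pathogenesis related protein5 (Zm00001d031158) on the same chromosome from 179966643 to 179967167. The phenylalanine ammonia lyase loci (Zm00001d017274, and Zm00001d017275 merged with Zm00001d017276) lie on chromosome 5 from 191418711 to 191422345 and from 191467430 to 191476907. The LHCII type III gene (Zm00001d021784) lies on chromosome 7 from 162969080 to 162970458, and the 2.1 gene (Zm00001d033132) on chromosome 1 from 251722257 to 251723494. The other named rises were Expansin-B4, a cell wall protein, with a log2 change of 2.87, undecaprenyl pyrophosphate synthetase with 2.52, root phototropism protein 2 with 2.26 and an F-box/kelch-repeat protein with 2.17. The other named falls were light harvesting chlorophyll binding protein9 (-3.64), light harvesting complex mesophyll7 (-3.13), light harvesting chlorophyll a/b binding protein3 (-3.08), the clock-related protein LNK1 (-2.96) and chlorophyllide a oxygenase (-2.95), which makes chlorophyll b. EdgeR adjusted p of these 9 loci ranged from 3.13e-10 to 0.000231.

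Photosystem and light-harvesting genes fell as a group in Mo17. Of 65 measured, 54 fell and 6 rose (55 and 6 adjusted over the list alone), with a median log2 change of -1.13. The size of the fall depended on the scaling: the median was -0.55 with library totals (43 lower and 7 higher), -0.53 with the authors' FPKM (43 and 9) and -0.69 with quantile normalization (46 and 6). Camera gave an adjusted p of 1.44e-95 (adjusted p = 0.00944 with an estimated correlation). The 6 that rose included a chlorophyll A-B binding family protein at 0.55. Calvin and C4 cycle genes had a median of -0.33, which turned to 0.24 with library totals and 0.14 with the authors' FPKM. Of 26, 12 were lower and 1 higher (14 and 1 adjusted over the list alone; adjusted p = 3.17e-05, and adjusted p = 0.147 with an estimated correlation). Among them phosphoenolpyruvate carboxykinase1, a C4 decarboxylase, fell from 854.9 ± 83.5 to 204.9 ± 19.2 CPM. Chlorophyll biosynthesis genes had a median of -0.09, which turned to 0.48 with library totals and 0.36 with the authors' FPKM. Of 28, 9 were lower and 5 higher, the same numbers adjusted over the list alone (adjusted p = 0.000254, and adjusted p = 0.178 with an estimated correlation). Mesophyll markers moved in both directions: pyruvate, orthophosphate dikinase1 fell by 1.06, whereas carbonic anhydrase6 rose by 0.65. The changes of phosphoenolpyruvate carboxylase1 (-0.46) and of a merged carbonic anhydrase locus (-0.31) turned positive with library totals, at 0.12 and 0.26. Bundle sheath markers moved in both directions too. Phosphoenolpyruvate carboxykinase1 fell, as given above. The Rubisco small subunit genes 1 and 2 changed by -0.36 and -0.29, which turned to 0.21 and 0.28 with library totals. The NADP-malic enzyme locus rose by 0.44 (edgeR adjusted p = 0.0275). That call ended without Mo17 mock replicate 1 or 3 (0.0781 and 0.0764) or infected Mo17 replicate 1 or 3 (0.105 and 0.0867).

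Of the defence and stress lists, 5 were called higher in Mo17, and 1 of these calls, that of the antioxidant list, held with an estimated correlation. Glutathione S-transferases and antioxidant enzymes had 29 higher and 7 lower of 147 (30 and 7 adjusted over the list alone). The median was 0.27 and the camera adjusted p 0.000707 (adjusted p = 0.00944 with an estimated correlation). In this group superoxide dismutase rose by 1.81 and catalase3, which removes hydrogen peroxide, fell by 1.40. Phenylpropanoid, lignin and flavonoid genes had 10 higher and 4 lower of 59 (11 and 4 adjusted over the list alone). The median was 0.31 and the adjusted p 0.00427 (adjusted p = 0.178 with an estimated correlation). Pathogenesis-related genes had 6 higher and 3 lower of 58, the same numbers adjusted over the list alone. The median was 0.41 and the adjusted p 0.0215 (adjusted p = 0.178 with an estimated correlation). RNA silencing genes had 6 higher and 2 lower of 35 (7 and 2 adjusted over the list alone). The median was 0.11 and the adjusted p 0.0295 (adjusted p = 0.160 with an estimated correlation), and argonaute1c was among the 2 lower ones at -0.79. Heat shock proteins and chaperones had 41 higher and 17 lower of 224 (42 and 19 adjusted over the list alone). The median was 0.15 and the adjusted p 0.0216 (adjusted p = 0.234 with an estimated correlation). A DNAJ heat shock N-terminal domain protein rose by 2.03 and a dnaJ-related chaperone fell by 2.21.

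Camera called the cytosolic ribosomal and proteasome lists higher in infected Mo17, although 187 of 253 and 53 of 71 members did not pass and both calls were lost with an estimated correlation. Cytosolic ribosomal proteins had 63 higher and 3 lower of 253 (78 and 6 adjusted over the list alone). The median was 0.34 and the camera adjusted p 1.11e-06 (adjusted p = 0.147 with an estimated correlation). The 40S ribosomal protein S9-2 rose by 1.11, and the list also caught a few plastid-encoded genes by symbol, such as rps14. Proteasome genes had 17 higher and 1 lower of 71 (21 and 1 adjusted over the list alone). The median was 0.20 and the adjusted p 0.00159 (adjusted p = 0.234 with an estimated correlation). Vascular and phloem markers had 4 higher and 0 lower of 15, also adjusted over the list alone. The median was 0.51 and the adjusted p 0.00492 (adjusted p = 0.0973 with an estimated correlation). Starch and sucrose genes had a median of -0.01, which turned to 0.54 with library totals, 0.24 with the authors' FPKM and 0.01 with quantile normalization. Of 77, 21 were lower and 7 higher (22 and 11 adjusted over the list alone; adjusted p = 0.0162, and adjusted p = 0.0973 with an estimated correlation). Senescence-associated genes had a median of -0.16, which turned to 0.40 with library totals and 0.20 with the authors' FPKM. Of 25, 7 were lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.0183, and adjusted p = 0.0973 with an estimated correlation). The cysteine protease SAG12, a marker of senescing leaves, fell from 24.1 ± 2.83 to 6.21 ± 0.572 CPM.

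No other list was called by camera in Mo17. Higher and lower members were 6 and 8 of 83 WRKY transcription factors (5 and 8 adjusted over the list alone; adjusted p = 0.754) and 8 and 4 of 69 NLR-type receptors (the same adjusted over the list alone; adjusted p = 0.406). They were 5 and 7 of 51 jasmonate genes (6 and 7 adjusted over the list alone; adjusted p = 0.895), where 12-oxo-phytodienoic acid reductase6 fell by 2.67. They were 2 and 1 of 11 benzoxazinoid genes (the same adjusted over the list alone; adjusted p = 0.285), 0 and 0 of 10 terpenoid defence genes (0.864) and 5 and 3 of 47 plastid ribosomal proteins (the same adjusted over the list alone; adjusted p = 0.698). Autophagy had 1 and 1 of 32 (0 and 0 adjusted over the list alone; adjusted p = 0.504), the circadian clock 1 and 6 of 23 (1 and 8 adjusted over the list alone; adjusted p = 0.236) and the cell cycle 10 and 5 of 103 (the same adjusted over the list alone; adjusted p = 0.271). Epidermal wax and cutin genes had 3 and 5 of 32 (4 and 5 adjusted over the list alone; adjusted p = 0.861), and auxin response 7 and 12 of 108 (the same adjusted over the list alone; adjusted p = 0.285). Initiation factors 4E and 4G had 2 and 1 of 7 (3 and 1 adjusted over the list alone; adjusted p = 0.556) and organelle-encoded genes 39 and 37 of 250 (42 and 42 adjusted over the list alone; adjusted p = 0.157). Median and mean differed in sign for the WRKY (-0.09 and 0.23; median 0.45 with library totals), autophagy (-0.15 and 0.03; median 0.43 with library totals) and wax lists (0.10 and -0.13; median -0.02 with TMM factors on FPKM). With TMM on counts, camera pointed up for WRKY and wax and down for autophagy, and with these other scalings the median of each turned.

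Of the genes tied to SCMV in earlier work, protein disulfide isomerase1 rose in Mo17 by 0.90 (SE 0.129; edgeR adjusted p = 0.000435). The gene named resistance to sugarcane mosaic virus1 (Zm00001d035390, chromosome 6 from 24034207 to 24035363) had 0.636 ± 0.607 CPM in Mo17 mock and 0.0353 ± 0.0306 CPM in infected Mo17, a log2 change of -4.15 (SE 0.733; edgeR adjusted p = 0.00190) that was -2.99 without Mo17 mock replicate 2. Its counts were 27, 141 and 30 in the mock libraries and 7, 7 and 0 in the infected ones. Auxin binding protein1 (-0.05), initiation factor 4E-1 (-0.07), catalase1 (-0.04), catalase2 (0.10), elongin C (0.24), ferredoxin3 (0.25), initiation factor isoform 4E (0.30) and polyamine oxidase1 (-0.40) did not pass the test.

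Infection of Mo17 changed 6145 of 32795 loci, 2847 higher and 3298 lower, and 1303 and 1739 of these changed at least 2-fold. Of the called loci with 1 annotated nuclear gene, 2564 were higher and 1978 lower, and in a fit on such loci alone the SCMV response in Mo17 had 2246 higher and 2400 lower. The split also depended on the scaling: with library totals 11196 loci were higher and 1196 lower, and with limma on the authors' FPKM 10957 were higher and 1412 lower.

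**Figure D1:**
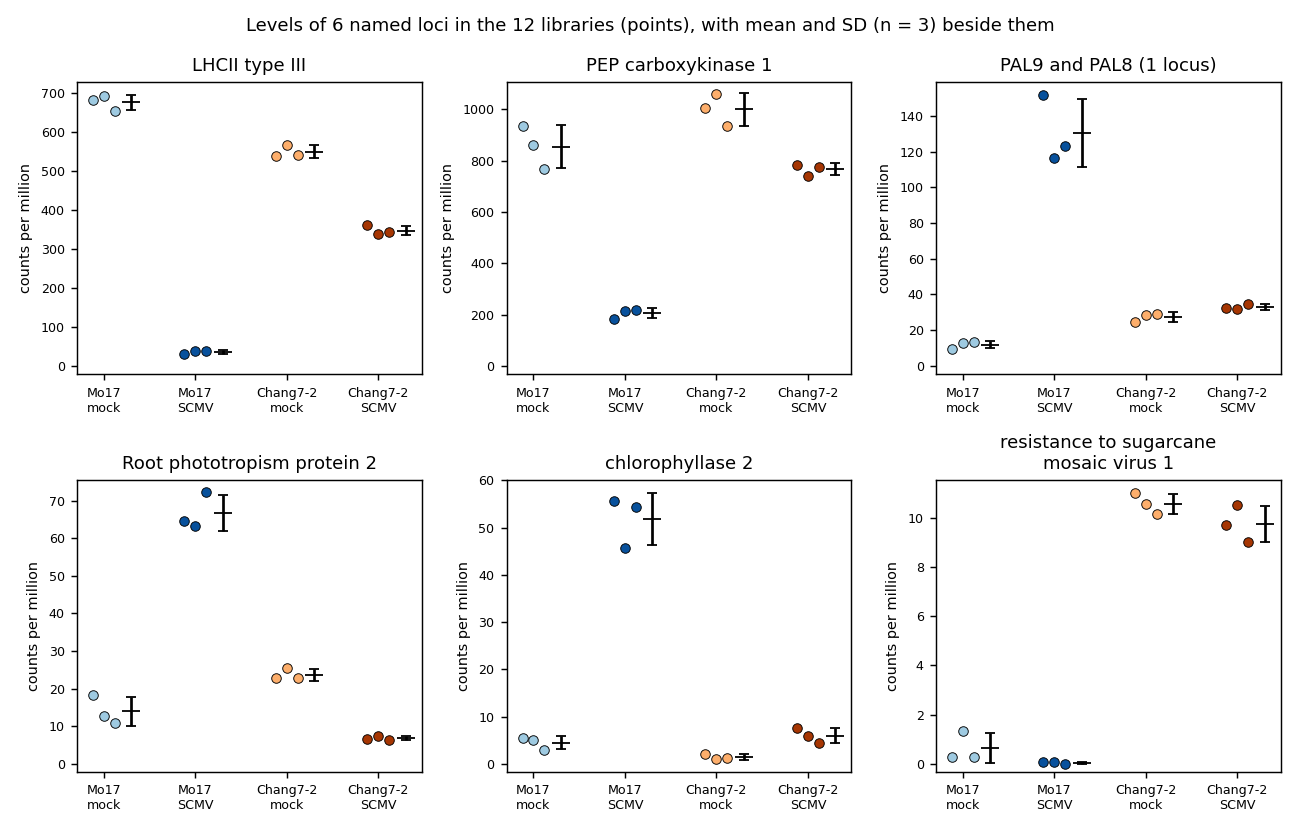
Counts per M of 6 loci in each of the 12 libraries, with points for libraries and the mean and SD of each group (n = 3). Chlorophyll a-b binding protein of LHCII type III stood at 35.7 CPM in infected Mo17 and 347.4 CPM in infected Chang7-2.

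In infected Chang7-2, the DNAJ heat shock N-terminal domain protein (Zm00001d026606, chromosome 10 from 148901682 to 148903753) rose from 7.02 ± 2.57 to 31.7 ± 4.43 CPM (mean ± SD, n = 3), a log2 change of 2.17 (SE 0.256; edgeR adjusted p = 0.000872). Chlorophyllase2 rose from 1.49 ± 0.608 to 6.02 ± 1.57 CPM, and monosaccharide-sensing protein 2, a sugar transporter of the vacuole, rose from 34.6 ± 4.70 to 107.7 ± 13.4 CPM. Protochlorophyllide reductase1 (Zm00001d001820, chromosome 2 from 1439871 to 1441447), an enzyme of chlorophyll synthesis, fell from 50.01 ± 10.1 to 13.6 ± 1.63 CPM, a log2 change of -1.88 (SE 0.216; adjusted p = 0.000845). Root phototropism protein 2 (Zm00001d005051, chromosome 2 from 156270103 to 156272641) fell from 23.7 ± 1.61 to 6.73 ± 0.536 CPM, and nitrate reductase(NADH)1 fell from 186.8 ± 37.7 to 59.1 ± 4.75 CPM.

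Further rises in Chang7-2 were those of 2 post-illumination chlorophyll fluorescence increase proteins (1.59 and 1.43), phosphoethanolamine N-methyltransferase 3 (1.47), temperature-induced lipocalin-1 (1.43) and a signal recognition particle RNA locus on chromosome 9, which had 0 estimated counts in the mock libraries and 8 in the infected ones. Further falls were those of DNA topoisomerase 2 (-3.63), lichenase-2 (-1.86), beta-amylase 3 (-1.86), which degrades starch, sugar carrier protein C (-1.77) and the nitrate transporter family protein NRT1/PTR 6.4 (-1.71). Calls of 5 of these loci ended in edgeR when 1 library was left out. For phosphoethanolamine N-methyltransferase 3 (Zm00001d011642) the adjusted p was 0.0567, 0.0525 and 0.0502 without mock replicate 2, mock replicate 3 or SCMV replicate 2 of Chang7-2, and for DNA topoisomerase 2 (Zm00001d002071) it was 0.0610 and 0.0603 without SCMV replicate 1 or 2. For sugar carrier protein C (Zm00001d021775) it was 0.0740, 0.0582, 0.0850 and 0.0880, and for beta-amylase 3 (Zm00001d047077) it was 0.135, 0.1201, 0.153 and 0.148, without mock replicates 2 or 3 or SCMV replicates 1 or 2 of Chang7-2. Beta-amylase 3 also reached 0.0598, 0.0596 and 0.0589 without infected Mo17 replicate 1, 2 or 3. For the signal recognition particle locus (MSTRG.24799) it was 0.0765, 0.125 and 0.111 without mock replicate 1, 2 or 3 and 0.0992 and 0.0953 without SCMV replicate 1 or 2 of Chang7-2. DNA topoisomerase 2 stood at 1.37, 2.69 and 7.65 CPM in Mo17 mock replicates 1, 2 and 3. Beta-amylase 3 stood at 28.4, 34.7 and 102.3 CPM there, and sugar carrier protein C at 13.5, 20.8 and 34.5 CPM. These 3 genes thus varied without infection, in the replicate order of the third principal component. How far their falls reflect SCMV rather than this variation was not tested. Lichenase-2 (30.2 to 46.7 CPM) and the nitrate transporter varied less in Mo17 mock.

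Starch and sucrose genes had 13 lower and 7 higher of 77 in Chang7-2 (20 and 9 adjusted over the list alone), with a median of -0.22, which was 0.00 with the authors' FPKM, and a camera adjusted p of 0.000417 (adjusted p = 0.0507 with an estimated correlation). WRKY genes had a median of -0.72 with 3 lower and 1 higher of 83 (13 and 3 adjusted over the list alone; adjusted p = 5.68e-06, and adjusted p = 0.376 with an estimated correlation). Photosystem and light-harvesting genes had a median of -0.12, which turned to 0.06 with library totals or the authors' FPKM. Of 65, 12 were lower and 0 higher (21 and 2 adjusted over the list alone; adjusted p = 0.00259, and adjusted p = 0.642 with an estimated correlation). In that list the LHCII type III gene fell by 0.66. Calvin and C4 cycle genes had a median of -0.12, which turned to 0.06 with library totals and 0.05 with the authors' FPKM. Of 26, 4 were lower and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 0.0485, and adjusted p = 0.578 with an estimated correlation), and Rubisco activase2 fell by 0.61. Auxin response genes had a median of -0.17, which turned to 0.01 with library totals. Of 108, 9 were lower and 3 higher (18 and 5 adjusted over the list alone; adjusted p = 0.0431, and adjusted p = 0.376 with an estimated correlation), and IAA15 fell by 1.12.

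Cytosolic ribosomal proteins had 5 higher and 0 lower of 253 in Chang7-2 (4 and 0 adjusted over the list alone). The median was 0.19 and the adjusted p 5.89e-06 (adjusted p = 0.376 with an estimated correlation). Plastid ribosomal proteins had 1 higher and 0 lower of 47 (0 and 0 adjusted over the list alone). The median was 0.15 and the adjusted p 0.00230 (adjusted p = 0.376 with an estimated correlation). Heat shock proteins and chaperones had 19 higher and 7 lower of 224 (25 and 11 adjusted over the list alone). The median was 0.12 and the adjusted p 0.0265 (adjusted p = 0.376 with an estimated correlation), and an HSP20-like chaperone fell by 1.11. The other 18 lists were not called. Protein disulfide isomerase1 (Zm00001d049099) rose by 0.60 (edgeR adjusted p = 0.0208), a call that ended without Chang7-2 mock replicate 2 (0.0613) or SCMV replicate 1, 2 or 3 (0.0549, 0.0903 and 0.0522). Catalase2 (Zm00001d027511) fell by 0.54 (adjusted p = 0.0190), a call that ended without mock replicate 2 or 3 (0.0868 and 0.0611) or SCMV replicate 1, 2 or 3 (0.0611, 0.0801 and 0.0572). Catalase3 (0.17), polyamine oxidase1 (0.53) and resistance to sugarcane mosaic virus1 (-0.12, 10.6 ± 0.412 and 9.75 ± 0.739 CPM) did not pass.

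Infection changed 1665 loci in Chang7-2, 772 higher and 893 lower, and 264 and 366 of these changed at least 2-fold. With library totals 1927 were higher and 457 lower, with limma on the authors' FPKM 2592 and 789, and with quantile normalization 1444 and 1068. The count was 531 or 546 without SCMV replicate 1 or 2 of Chang7-2, 578 or 671 without its mock replicate 2 or 3, and 3245 without the first mock library of each line. Of the loci changed in both lines, 386 were higher in both, where 67.0 would overlap if the responses were independent, and 446 were lower in both, where 89.8 would. Opposite changes were fewer: 31 loci were higher in Mo17 and lower in Chang7-2, and 22 the reverse. Loci called in Mo17 had a median absolute log2 change of 0.99 there and 0.31 in Chang7-2, with the same sign in 72.9%. Loci called in Chang7-2 had 0.84 there and 0.60 in Mo17, with the same sign in 80.3%, and each set favours the line in which it was chosen.

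Among loci that met the naming rule, the response differed most between the lines at root phototropism protein 2, which rose in Mo17 and fell in Chang7-2, a log2 difference (Mo17 minus Chang7-2) of 4.08 (SE 0.233; edgeR adjusted p = 1.12e-06). The phenylalanine ammonia lyase9 and 8 locus differed by 3.21 and homolog1 by 2.79: in Chang7-2 they stood at 27.3 ± 2.63 and 57.5 ± 3.17 CPM in mock and at 32.8 ± 1.56 and 62.4 ± 4.63 CPM under infection (mean ± SD, n = 3). Arginine decarboxylase, an enzyme of polyamine synthesis, differed by 2.71 and NaCl stress protein1 by 2.98 (3.79 without Mo17 mock replicate 3). Responses were lower in Mo17 for the LHCII type III gene (-3.58), photosystem II light harvesting complex gene 2.1 (-3.40), light harvesting chlorophyll binding protein9 (-3.18) and nine-cis-epoxycarotenoid dioxygenase8 and 6 (-3.16 and -2.85), which form the precursor of abscisic acid. The NaCl stress protein1 (Zm00001d024778) call (adjusted p = 0.0422) ended without Chang7-2 mock replicate 2 (0.111) or 3 (0.0783), Mo17 mock replicate 2 (0.0948), Chang7-2 SCMV replicate 1 (0.104) or 2 (0.0980), or infected Mo17 replicate 1 (0.0705), 2 (0.0777) or 3 (0.102).

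Among the lists, photosystem and light-harvesting genes responded more negatively in Mo17, with 49 lower and 3 higher of 65 (56 and 4 adjusted over the list alone), a median difference of -1.03 and a camera adjusted p of 2.41e-87 (adjusted p = 0.0158 with an estimated correlation). That median was -0.64 with library totals, -0.63 with the authors' FPKM and -0.61 with quantile normalization. Glutathione S-transferases and antioxidant enzymes responded more positively, with 17 higher and 3 lower of 147 (20 and 4 adjusted over the list alone). The median was 0.34 and the adjusted p 0.00326 (adjusted p = 0.0158 with an estimated correlation). The other 7 calls were lost with an estimated correlation. These were WRKY genes (0.68; 4 higher and 2 lower, 6 and 2 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), vascular markers (0.52; 3 and 0, 6 and 0 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation) and pathogenesis-related genes (0.38; 3 and 2, 6 and 2 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation). They were also cell cycle genes (0.34; 5 and 0, also adjusted over the list alone; adjusted p = 0.543 with an estimated correlation) and the proteasome (0.16; 3 and 0, 2 and 0 adjusted over the list alone; adjusted p = 0.543 with an estimated correlation). Calvin and C4 genes (-0.23; 0.16 with library totals, 0.15 with the authors' FPKM and 0.03 with quantile normalization) had 7 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation). Chlorophyll biosynthesis genes (-0.19; 0.23 with library totals and 0.16 with the authors' FPKM) had 7 lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation).

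In all, the responses differed at 1963 loci, 865 higher and 1098 lower in Mo17, with 585 and 638 at least 2-fold apart. Of the called loci with 1 annotated nuclear gene, 783 were higher and 719 lower, and in a fit on such loci alone the difference of the SCMV response between lines had 747 higher and 884 lower. With library totals 3323 were higher and 489 lower, and with limma on the authors' FPKM 5083 and 1049. The count was 1157 or 1204 without SCMV replicate 2 or 1 of Chang7-2, 1247 without its mock replicate 2, 1276 without infected Mo17 replicate 3 and 3154 without Mo17 mock replicate 3.

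**Figure D2:**
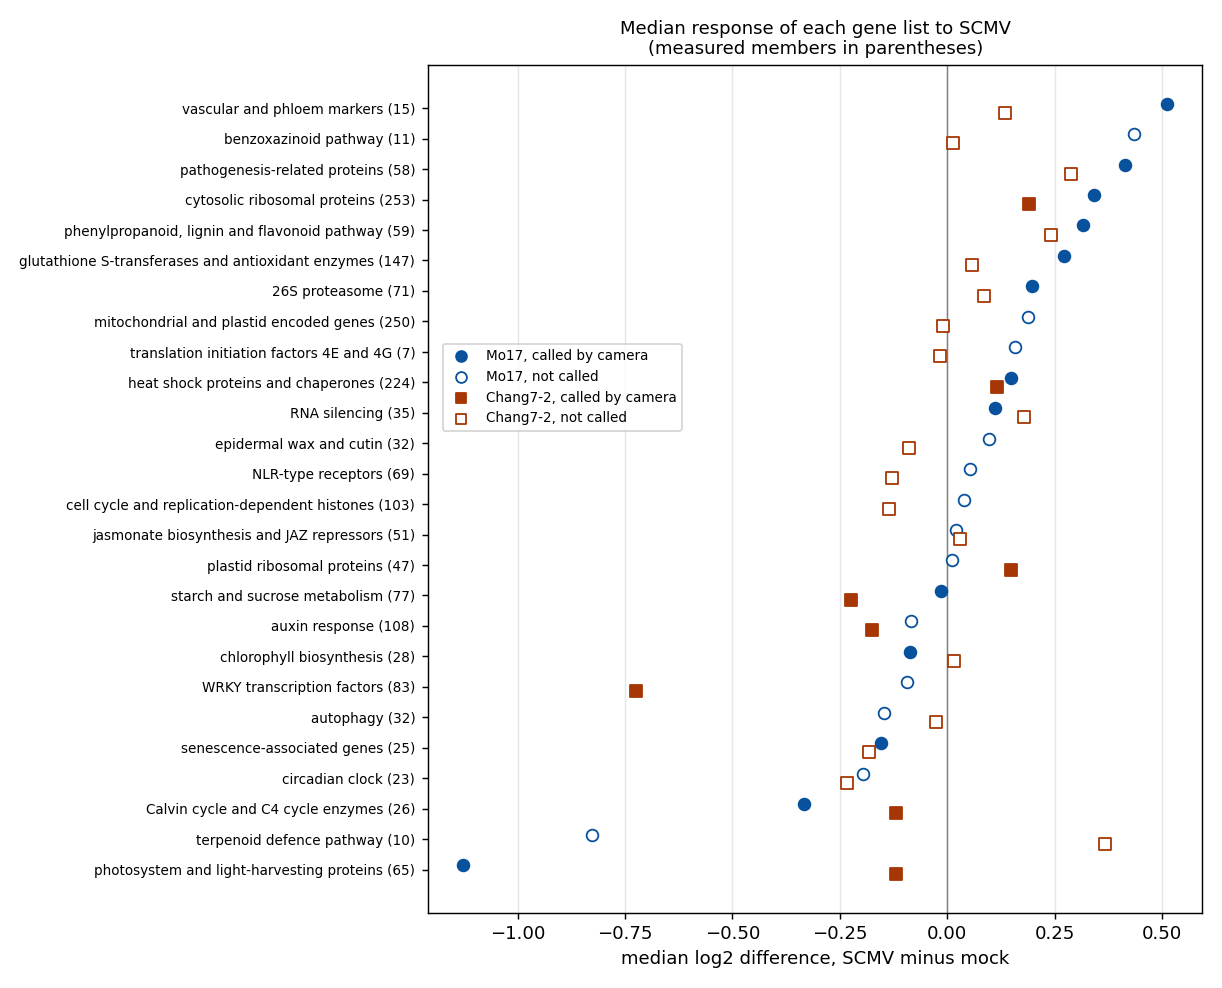
Median log2 change under infection of the members of 26 gene lists in Mo17 (circles) and Chang7-2 (squares), filled where camera called the list with the preset correlation. The photosystem and light-harvesting list stood at -1.13 in Mo17 (-0.55 with library totals) and at -0.12 in Chang7-2, where it turned to 0.06 with library totals; medians of 12 lists in Mo17 changed sign under at least 1 other scaling.

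Without infection, the lines differed at many loci that were near 0 in one of them. Higher in Chang7-2 were a RING-type zinc finger family protein (34.9 ± 0.695 against 0.263 ± 0.219 CPM; mean ± SD, n = 3), abscisic acid stress ripening5 (46.6 ± 13.4 against 0.381 ± 0.272 CPM), a putative cyclotide family protein (5.15 ± 0.461 against 0.0690 ± 0.00607 CPM) and gamma-glutamylcyclotransferase 2-2 (7.38 ± 2.57 against 0.136 ± 0.0768 CPM). Their log2 differences were 7.01, 6.92, 6.21 and 5.74, with edgeR adjusted p of 1.56e-09 to 2.56e-06, and without Mo17 mock replicate 3 the first 2 were 7.76 and 7.70. Pathogenesis related protein5 was lower in Chang7-2, at 0.0604 ± 0.0473 against 12.2 ± 2.19 CPM, a log2 difference of -7.58 (SE 0.352; adjusted p = 1.77e-08; -8.47 without Chang7-2 mock replicate 1). Nodulin-related protein 1 (2 against 2828 estimated counts over the 3 libraries) and ferredoxin-1 (3 against 2073) were lower, and a mitochondrial reading frame, orf99-d, was lower by a log2 difference of -9.11.

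Several loci labelled as structural RNAs or a microRNA precursor were among the largest differences between the mock-treated lines; they were named by size and not tested as a group. Higher in Chang7-2 were a signal recognition particle RNA on chromosome 1 (9.79), a U2 (7.61), a U1 (7.40) and a U3 (6.18) RNA. With 1 library left out these values ranged from 9.21 to 10.35, 7.02 to 8.92, 6.82 to 7.88 and 5.81 to 6.71. In Mo17 mock replicates 1, 2 and 3 the first locus had 0.0326, 0 and 0.0370 CPM and the U2 RNA 0.0326, 0 and 0.0833 CPM. The U1 RNA had 0.0326, 0 and 0.0278 CPM there and the U3 RNA 0.0977, 0.209 and 0.0833 CPM, so these log2 differences rest on few counts. Lower in Chang7-2 were another U1 RNA, with 4 estimated counts in Chang7-2 mock, all in replicate 3, against 1102 in Mo17 mock, and the signal recognition particle RNA on chromosome 9 (0 against 1947). Both loci of the microRNA precursor zma-MIR528a were lower too (2 against 2594 and 7 against 725). Resistance to sugarcane mosaic virus1 was higher in Chang7-2 by 4.04 (SE 0.517; edgeR adjusted p = 4.73e-05; 5.21 without Mo17 mock replicate 2) and elongin C by 2.36 (SE 0.249; adjusted p = 1.05e-05). The initiation factor 4E-1 locus was lower in Chang7-2 mock, with 5 estimated counts, all in replicate 1, against 449 in Mo17 mock. Catalase3 was lower in Chang7-2 by a log2 difference of -0.76 and polyamine oxidase1 by -0.68, and catalase2 was higher by 1.21.

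Jasmonate genes were higher in Chang7-2 mock, with 27 higher and 5 lower of 51, the same adjusted over the list alone, a median of 0.82 and a camera adjusted p of 0.00224 (adjusted p = 0.518 with an estimated correlation). Linoleate 9S-lipoxygenase 1 (Zm00001d042540, chromosome 3 from 171277704 to 171281453) stood at 57.3 ± 7.29 against 3.91 ± 2.49 CPM. Organelle-encoded genes had 118 higher and 16 lower of 250 (121 and 16 adjusted over the list alone). The median was 0.44 and the adjusted p 0.000931 (adjusted p = 0.518 with an estimated correlation). Kaurene oxidase2 (Zm00001d046342, chromosome 9 from 81729257 to 81733312), an enzyme of diterpenoid synthesis, stood at 12.3 ± 2.10 CPM in Chang7-2 and 0.347 ± 0.291 CPM in Mo17. Of the cell type markers, Rubisco small subunit genes 1 and 2 (0.79 and 0.73), carbonic anhydrase5 (0.83) and phosphoenolpyruvate carboxylase1 (0.25) were higher in Chang7-2. NADP-malic enzyme (0.31), carbonic anhydrase6 (-0.15) and carbonic anhydrase4 (-0.12; 0.01 with library totals) did not pass. The merged carbonic anhydrase locus (0.19; -0.09 with quantile normalization) was not called without Chang7-2 mock replicate 2 (edgeR adjusted p = 0.0718) or Mo17 mock replicate 3 (0.0519). Phosphoenolpyruvate carboxykinase1 (0.23) was not called without Chang7-2 mock replicate 1 or 2 (0.0864 and 0.156), Mo17 mock replicate 2 or 3 (0.0869 and 0.165) or Chang7-2 SCMV replicate 1 or 2 (0.0605 and 0.0605). Pyruvate, orthophosphate dikinase1 (0.18) was not called without Chang7-2 mock replicate 2 or 3 (0.149 and 0.0880), Mo17 mock replicate 2 or 3 (0.165 and 0.130) or Chang7-2 SCMV replicate 1 or 2 (0.0568 and 0.0619). In all, 15105 loci differed without infection, 7644 higher in Chang7-2 and 7461 lower, with 5532 and 5421 at least 2-fold apart. Reads of both lines were counted at loci of one reference, and no test of how sequence variants of a line affect its counts was run.

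Between the infected lines, herbicide safener binding protein1 stood at 106.3 ± 6.79 CPM in Chang7-2 and 0.441 ± 0.0592 CPM in Mo17 (mean ± SD, n = 3), a log2 difference of 7.91 (SE 0.391; edgeR adjusted p = 2.18e-08). Also higher in Chang7-2 were the signal recognition particle RNA on chromosome 1 (7.99), the cyclotide family protein (7.83), the U2 RNA (7.44; 6.99 to 8.99 with 1 library left out) and the RING-type zinc finger protein (6.01). Lower were a zma-MIR528a locus (0 estimated counts in infected Chang7-2 against 1599 in infected Mo17), a U1 RNA (0 against 1101), nodulin-related protein 1 (3 against 3140), ferredoxin-1 (6, all in replicate 3, against 5361) and orf99-d (-9.68; -10.36 without Chang7-2 SCMV replicate 2). In infected Mo17 the signal recognition particle RNA on chromosome 1 had 0.0800, 0.0235 and 0.0816 CPM. The U2 RNA had 0.0800, 0.0157 and 0.00742 CPM there, so both log2 differences rest on few counts. Photosystem and light-harvesting genes were higher in infected Chang7-2, with 53 higher and 2 lower of 65 (54 and 2 adjusted over the list alone). The median was 0.87 (0.42 with quantile normalization) and the camera adjusted p 3.69e-21 (adjusted p = 0.256 with an estimated correlation). Calvin and C4 genes had 18 higher and 5 lower of 26, also adjusted over the list alone, and a median of 0.75 (adjusted p = 0.00155, and adjusted p = 0.341 with an estimated correlation). RNA silencing genes leaned lower in Chang7-2 without infection as well (12 lower and 6 higher, median -0.31, camera adjusted p = 0.202). Their difference of responses was not called (camera adjusted p = 0.0707). Under infection they had 17 lower and 5 higher of 35, also adjusted over the list alone, and a median of -0.75 (adjusted p = 0.0170, and adjusted p = 0.256 with an estimated correlation). Jasmonate genes had 22 higher and 9 lower of 51 (23 and 10 adjusted over the list alone) and a median of 0.49 (adjusted p = 0.00963, and adjusted p = 0.256 with an estimated correlation), and organelle-encoded genes 114 and 14 of 250 (114 and 15 adjusted over the list alone) and a median of 0.34 (adjusted p = 0.00963, and adjusted p = 0.469 with an estimated correlation).

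In all, 15733 loci differed between the infected lines, 7926 higher in Chang7-2 and 7807 lower, with 5624 and 5694 at least 2-fold apart. Of the called loci with 1 annotated nuclear gene, 4453 were higher and 4768 lower. A fit on such loci alone (Chang7-2 against Mo17 under infection) had 4487 higher and 4180 lower. With library totals 6092 were higher and 10852 lower, and with limma on the authors' FPKM 5183 and 9940. Of the loci higher in Chang7-2, 5593 were called with and without infection, where 1847 would be if the calls were independent, and of those lower, 5505 were, where 1776 would be. Both comparisons set the same lines against each other at the same loci in a shared fit, so independence serves only as a reference value.

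Circular RNAs (circRNAs) were counted by back-splice reads, which join a downstream site to an upstream one. The authors classed 1732 of them as circRNA, 1262 (39.3%) as ciRNA and 214 (6.67%) as intergenic, and all are called circRNAs here. The largest count belonged to circRNA483, which spans 30 exons of a locus of an RNA polymerase III subunit on chromosome 6, from 62651061 to 62672025, and had 577 to 721 counts in Mo17 libraries and 0 to 3 in Chang7-2 libraries. Without infection it was 741 times lower in Chang7-2 (95% counting interval 253 to 3594; edgeR adjusted p = 2.62e-07). All 3 of its Chang7-2 mock counts came from replicate 2: the log2 difference of -9.31 was -8.67 without replicate 1 and -12.47 without replicate 2, where 0 counts remain and the value is no bound. Its host locus (Zm00001d035960) was lower in Chang7-2 too, at 13.6 ± 2.30 against 212.0 ± 5.97 CPM (mean ± SD, n = 3). The nearly identical ciRNA365 was at least 21.8-fold lower. Circles of 2 exons of kaurene oxidase2, circRNA186 and circRNA139, are also nearly identical, with 1 end in common and the other 1 base apart. They had 301 and 194 counts in Chang7-2 mock and 0 in Mo17 mock, at least 85.9-fold and 55.3-fold higher, and their host gene was higher by 5.17 (4.61 to 5.82 with 1 library left out).

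Of 361 circRNAs tested, 14 were higher and 7 lower in Chang7-2 without infection. Others with large differences were circRNA248, circRNA180 and circRNA339 (at least 31.7-fold, 29.1-fold and 26.2-fold higher) and circRNA891, circRNA945 and circRNA1088 (at least 19.1-fold, 11.7-fold and 10.5-fold lower). Without Mo17 mock replicate 3 the adjusted p of circRNA248 was 0.0627, and without Mo17 mock replicate 2 that of circRNA945 was 0.0699. That of circRNA1088 was 0.0610 and 0.0929 without Chang7-2 mock replicate 2 or 3, 0.127 and 0.203 without Mo17 mock replicate 2 or 3, and 0.0883 and 0.114 without infected Mo17 replicate 1 or 3. The count of 21 was 12 without Mo17 mock replicate 2 or 3, and 54 in a fit on the 6 mock libraries alone.

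Infection changed 0 circRNAs by edgeR in either line, with 19 in Mo17 and 14 in Chang7-2 at an unadjusted p under 0.05, and DESeq2 called 0 as well. The smallest p in Mo17 belonged to circRNA295 (0 counts in mock and 15 under infection), circRNA197 (0 and 18) and circRNA272 (28 and 0), each with an adjusted p of 0.546. In Chang7-2 they belonged to ciRNA76 (4 and 64), circRNA232 (20 and 0) and circRNA507 (24 and 0), each with an adjusted p of 0.858. Detected circRNAs numbered 397 ± 33.6 in Mo17 mock and 367.7 ± 15.3 under infection (SD, n = 3; two-sided exact permutation p = 0.2), and 439 ± 27.2 and 467.3 ± 26.4 in Chang7-2 (exact p = 0.2). Total back-splice counts were 1983 ± 208 and 1939 ± 130 in Mo17 (exact p = 0.9) and 1950 ± 29.9 and 1924 ± 206 in Chang7-2 (exact p = 1). With 3 libraries against 3 the smallest possible p is 0.1. Of 3208 circRNAs listed, 2534 (79.0%) had counts in 1 library and 15 in all 12, so most were too sparse for a test.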

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

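The tests of cell type, scaling and senescence for the photosynthesis genes, of a single library for resistance to sugarcane mosaic virus1, and of other back-splice reads for circRNA483 were chosen only after the results were seen, as were the reference loci and bootstrap conditions of all tests. Each gene and list in this part drew attention because its response to SCMV differed between Mo17 and Chang7-2 in a direct edgeR test of that difference (Benjamini-Hochberg adjusted), or, for lists, in camera. Values are log2 differences, Mo17 minus Chang7-2.

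The signs of the 2 estimated responses were opposite for 13 genes, among them root phototropism protein 2 (4.08), NaCl stress protein1 (2.98), arginine decarboxylase (2.71), the F-box/kelch-repeat protein (2.49) and peroxidase 53 (1.30). Neither response had to be called to enter this count. Some responses were near 0, such as those of benzoxazinone synthesis4 (0.01) and carbonic anhydrase6 (-0.03) in Chang7-2. Polyamine oxidase1 passed in neither line. Responses were higher in Mo17 for the phenylalanine ammonia lyase9 and 8 locus (3.21) and homolog1 (2.79), undecaprenyl pyrophosphate synthetase (2.04), Expansin-B4 (1.97), lichenase-2 (1.69), chlorophyllase2 (1.51), phospholipid transfer protein homolog2 (1.40) and superoxide dismutase (1.23). Smaller differences of this sign belonged to the 40S ribosomal protein S9-2 (0.99), orf444 (0.96), carbonic anhydrase6 (0.68), catalase2 (0.65), shrunken1 (0.57) and a chlorophyll A-B binding family protein (0.55). A higher response need not be a rise in Mo17. Lichenase-2 changed by -0.17 in Mo17 and -1.86 in Chang7-2, and catalase2 by 0.10 and -0.54. Nor need a lower response be a fall in Mo17. The post-illumination chlorophyll fluorescence increase protein listed below changed by 0.11 in Mo17 and 1.43 in Chang7-2.

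Responses were lower in Mo17 for resistance to sugarcane mosaic virus1 (-4.03), the LHCII type III gene (-3.58), photosystem II light harvesting complex gene 2.1 (-3.40), light harvesting chlorophyll binding protein9 (-3.18), nine-cis-epoxycarotenoid dioxygenase8 (-3.16) and 6 (-2.85), light harvesting complex mesophyll7 (-2.84), aluminum-induced protein homolog1 (-2.78) and light harvesting chlorophyll a/b binding protein3 (-2.70). They were also lower for chlorophyllide a oxygenase (-2.37), 12-oxo-phytodienoic acid reductase6 (-2.21), a dnaJ-related chaperone (-1.9625), SAG12 (-1.87), LNK1 (-1.70), phosphoenolpyruvate carboxykinase1 (-1.68), catalase3 (-1.57) and a post-illumination chlorophyll fluorescence increase protein (-1.33). Smaller differences of this sign belonged to a 3-ketoacyl-CoA synthase (-0.94), polyamine oxidase1 (-0.93), IAA27 (-0.83), pyruvate, orthophosphate dikinase1 (-0.80), the clock regulator APRR3 (-0.70), benzoxazinone synthesis4 (-0.67), cinnamyl alcohol dehydrogenase 6 (-0.66), sucrose phosphate synthase1 (-0.58), rps14 (-0.47), argonaute1c (-0.42) and phosphoenolpyruvate carboxylase1 (-0.34). With library totals the Mo17 responses of rps14 and phosphoenolpyruvate carboxylase1 turned to 0.04 and 0.12, so the smallest of these differences may depend on scaling.

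Lists that camera called for the difference with the preset correlation were photosystem and light-harvesting proteins (-1.03), Calvin and C4 cycle enzymes (-0.23; 0.16 with library totals), chlorophyll biosynthesis (-0.19; 0.23 with library totals), WRKY factors (0.68), vascular markers (0.52), pathogenesis-related proteins (0.38), glutathione S-transferases and antioxidant enzymes (0.34), cell cycle and histones (0.34) and the proteasome (0.16). With an estimated correlation 2 of the 9 calls held, those of the photosystem and the antioxidant lists (camera adjusted p = 0.0158 for both), and the other 7 were lost (0.137 to 0.543).

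The fall of photosystem and light-harvesting transcripts in infected Mo17 was set against 3 other explanations. A smaller share of mesophyll cells alone would lower all mesophyll markers alike. The 6 markers fell less than the list, with a median log2 change of -0.442 (95% bootstrap interval over markers -0.762 to 0.172) against -1.13. Markers can also change within cells, so these values do not measure the share of cells, and this explanation stays open. With library totals the median of the 65 genes was still -0.548 (-0.853 to -0.362), which argues against scaling as the whole cause and leaves part of the size to it. The senescence list had a median of -0.155 (-0.553 to 0.0254), which left more advanced senescence open.

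Resistance to sugarcane mosaic virus1 stood in Mo17 mock at 6.02% of its level in Chang7-2 mock. RNA of Chang7-2 in the Mo17 mock libraries would have raised other loci of a like level to the same share, but the median over 49 of them was 0 (0 to 0.113), which argues against it. Without Mo17 mock replicate 2, which held the highest count, the adjusted p (edgeR) was 0.00185 against 0.00190 with it, so the call did not rest on that library. The size did in part: the log2 change was -2.99 in place of -4.15, and the difference of -4.03 between lines rests on the same libraries. Over all alternatives (Zm00001d035390, SCMV response in Mo17) adjusted p ranged from 1.19e-06 to 0.0414. No biological explanation was tested.

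For circRNA483, the host locus was 15.6-fold higher in Mo17 mock (13.1 to 18.6), which goes with a host gene expressed mainly in Mo17. The host counts include reads of the circle itself, and the host still had 13.6 CPM in Chang7-2, so the rest of the ratio of 741 stays open. Other back-splice reads were more numerous in Chang7-2 than in Mo17 libraries (ratio 1.49; 1.35 to 1.64), which argues against fewer circular reads in Chang7-2. These totals were not scaled by mapped reads, which were 30.9 to 35.5 M in Mo17 and 34.7 to 40.2 M in Chang7-2 libraries. A sequence variant of a line against the reference was not tested.

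Libraries were also regrouped. Of the 10 ways to split 6 libraries into 3 and 3, the number with at least the real count of calls (real count, highest other) was 1 for Mo17 (5172, 0), 1 for Chang7-2 (2012, 1), 1 for the mock-treated lines (12060, 5) and 1 for the infected lines (16570, 0). For lists it was 1 in Mo17 (10, 7), 1 in Chang7-2 (7, 5), 9 for mock-treated lines (2, 7) and 1 for infected lines (5, 4), and for circRNAs 10 in Mo17 (0, 0), 10 in Chang7-2 (0, 1) and 1 for mock-treated lines (54, 0). With 10 splits there are too few for a share under 0.05.

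For the difference of the responses, 3 of 60 draws of treatment labels reached the real count of 1963 calls, with a highest other count of 6372. For lists 9 of 60 draws reached the real count of 9, with a highest other count of 14. All draws with more than 2 calls kept the labels of Mo17, and all with more than 6 lists kept those of at least 1 line, and so carry a real response. The draw with 6372 reverses the labels of Chang7-2, which adds the responses. Draws that kept the labels of neither line gave 0 to 2 calls and 0 to 6 lists, but they mix mock and infected libraries in each group, which widens the spread. In the simulated data 4 unchanged loci of 31842 were called for this comparison. That simulation drew independent noise from the same model that was then fitted, so few such calls were built in. It checks the fit and does not bear on the source of the 1963 calls. It also holds no variation shared by the loci of a library. Whether chance is excluded for the difference therefore stays open.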

How the results depend on the processing

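Of 5935 alternative values for 247 results (a named gene or circRNA in 1 comparison), 5349 kept the direction and side of the threshold. The direction was kept but the call was lost in 315 and gained in 86. The direction turned in 53 where the main or the alternative fit made a call (reversed), and in 132 where neither did. The cause was not tested for any value that follows, except where fewer loci or a size threshold lower a count by construction. TMM and library totals differ most in infected Mo17, so small changes there depend on scaling.

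Reversed values (log2, Mo17 response; limma on FPKM with pseudocounts 1, 0.5 and 0.1, then library totals) were RIN4 0.0944, 0.101, 0.108 and 0.108, 30S ribosomal protein S16 0.0199, 0.0208, 0.0216 and 0.0158, initiation factor 4G 0.19, 0.21, 0.22 and 0.22, catalase1 0.48, 0.50, 0.53 and 0.53, the merged carbonic anhydrase locus 0.26, 0.26, 0.26 and 0.26, carbonic anhydrase5 0.11, 0.13, 0.15 and 0.14, and carbonic anhydrase4 0.0818, 0.0937, 0.106 and 0.113. With quantile normalization added as the last value they were rps14 0.0446, 0.0446, 0.0446, 0.0442 and 0.169, Rubisco small subunit 1 0.22, 0.22, 0.22, 0.21 and 0.28, phosphoenolpyruvate carboxylase1 0.12, 0.12, 0.12, 0.12 and 0.16, and Rubisco small subunit 2 0.29, 0.29, 0.29, 0.28 and 0.29. Auxin binding protein1 gave 0.23, 0.32 and 0.49 with the 3 pseudocounts and the initiation factor 4E-1 locus 0.30 with a pseudocount of 1. Between the mock-treated lines, the merged carbonic anhydrase locus gave -0.0938 with quantile normalization.

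The count of 6145 for the SCMV response in Mo17 was 12369, 12387 and 12118 with limma on FPKM (pseudocounts 1, 0.5 and 0.1), 12392 with library totals, 1352 at a mean FPKM of at least 5 and 3042 at a log2 size of at least 1, and 4148 to 6417 with 1 library left out. The count of 1665 for the SCMV response in Chang7-2 was 3381, 3317 and 3018 with limma, 2609 with TMM on FPKM, 2512 with quantile normalization, 3531 with DESeq2, 3245 without both first mock libraries, 548 at a mean FPKM of at least 5, 630 at a log2 size of at least 1, and 531 to 2408 with 1 library left out (578 and 671 without mock replicate 2 or 3, 531 and 546 without SCMV replicate 1 or 2).

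The count of 1963 for the difference of the SCMV response between lines was 6132, 5866 and 5097 with limma, 3281 with TMM on FPKM, 3212 with quantile normalization, 3540 with DESeq2, 3812 with library totals, 876 at a mean FPKM of at least 5, 1223 at a log2 size of at least 1, and 1157 to 3154 with 1 library left out (1247 without Chang7-2 mock replicate 2, 1204 and 1157 without its SCMV replicate 1 or 2, 1276 without infected Mo17 replicate 3, 3154 without Mo17 mock replicate 3). Between mock-treated lines the count of 15105 was 1297 at a mean FPKM of at least 5, 8196 over loci of 1 annotated nuclear gene and 13269 to 15224 with 1 library left out. Between infected lines the count of 15733 was 1505, 8667 and 13792 to 16443.

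Camera called 13, 8, 9, 2 and 5 lists in Mo17, Chang7-2, the difference, the mock-treated and the infected lines, and 2, 0, 2, 0 and 0 with an estimated correlation. The 13 were 8 with TMM on FPKM, and the 9 were 5 with a pseudocount of 0.1. For circRNAs the count of 0 in Chang7-2 was 1 without SCMV replicate 3, and the count of 21 was 12 to 24 with 1 library left out (12 without Mo17 mock replicate 2 or 3) and 54 in a fit on the 6 mock libraries alone. The difference in the number of circRNAs in Chang7-2, 28.3, was -11.0 over circRNAs in at least 3 libraries and 18.3 to 43.8 with 1 library left out. The pseudocount alternative for circRNAs was not run, since the table holds counts.

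With a replicate block, counts were 5837, 1777, 1993, 14783 and 15511 for genes, 9, 9, 11, 2 and 5 for lists, and 0, 0 and 21 for circRNAs. Libraries of the same number correlated at -0.0248 to 0.0446 within lines and -0.0719 to 0.114 between lines, the highest for the first mock libraries (0.114) and the third (0.0908), and 5 of 12 matched their own number best, a hint that the numbers do not pair libraries throughout. The block changed no other call by over 1.5 times. Of 3208 circRNAs, 361 had counts in at least 3 libraries and could be tested, and whether depth is the reason was not tested.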

Other observations

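The 4 genes named here were picked after the data were seen, because each fell in infected Mo17 and did not pass in infected Chang7-2; they stand for no group, and the senescence list had 1 higher and 2 lower members in Chang7-2. Their differences of response were tested in edgeR (-2.85, -3.16, -1.57 and -1.87 in the order given). Nine-cis-epoxycarotenoid dioxygenase6 (Zm00001d051556) stood at 218 ± 57.9 CPM in Mo17 mock and 29.3 ± 5.86 CPM under infection (mean ± SD, n = 3), and at 119 ± 6.62 and 115 ± 11.2 CPM in Chang7-2. Nine-cis-epoxycarotenoid dioxygenase8 (Zm00001d017766) stood at 29.6 ± 3.89 and 4.87 ± 1.09 CPM in Mo17 and at 28.9 ± 9.45 and 42.5 ± 4.97 CPM in Chang7-2. Catalase3 (Zm00001d054044) stood at 262 ± 39.2 and 99.2 ± 7.71 CPM in Mo17 and at 155 ± 10.95 and 174 ± 0.975 CPM in Chang7-2. The cysteine protease SAG12 (Zm00001d049113) stood at 56.9 ± 3.87 and 53.5 ± 5.57 CPM in Chang7-2, above its levels of 24.1 ± 2.83 and 6.21 ± 0.572 CPM in Mo17.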
